A study of Mus musculus with 6 samples.

How the data were processed

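Endometrium was collected on day 4 of pregnancy from mice injected for 20 days with dehydroepiandrosterone (DHEA, an androgen precursor given at 6 mg per 100 g per day in 0.2 mL soybean oil) or with oil alone, per the labels. The labels give the age of the mice as 4 weeks. Mating took place on day 21. Each sample pooled endometrium of 3 mice, and 6 pools were analysed here, 3 per group. The labels name 24 mice, 12 per group. Groups and replicate numbers were taken from the sample titles. The labels do not say that the pools of a group held different mice, although 12 mice per group allow it, so p-values measure the spread between these pools.

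Per the labels' protocols, total RNA was digested with RNase R, an exonuclease that degrades linear RNA, and the remaining RNA was labelled with Cy3 by random priming. Per the file headers, the deposited scanner files came from Agilent Feature Extraction 11.0.1.1 and hold 1-colour spot intensities, including a background-subtracted processed intensity, a median intensity and flags. The submitters' processing notes also name limma, with no version. The authors' series table holds log2 values for 14236 circRNA probes, with array medians between 6.86 and 6.88. Its columns ranked probes almost as the median intensities did (Spearman correlations across probes above 0.999), and the median absolute difference from quantile-normalised log2 median intensities was between 0.027 and 0.034. The exact normalization behind that table stays unknown. It served as an alternative only.

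The main measure was log2 of the processed intensity minus the 75th percentile over the circRNA probes of the same array. Spots flagged as outliers were left out, and spots of 1 probe were averaged. A circRNA probe was kept when well above background on at least 3 of the 6 arrays, and tested with at least 2 unflagged values in each group. Of 14236 circRNA probes, 40 were too dim and 29 lacked unflagged values, which left 14167. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. A looser list took probes at an unadjusted p under 0.05 and a fold of 1.5 or more. Single values per array were compared with two-sided exact permutation tests, whose smallest p with 3 arrays against 3 is 0.1.

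The array also carries 50 probes that the files pair with mRNA accessions, 14 probes named as circRNA controls, 15 custom probes and 15 probes named as negatives. These were tested in the same way, each kind on its own, without the filter on dim probes. The RefSeq gene table (assembly GRCm38.p6) gave symbols for 44 of the 50 mRNA accessions. These probes were found in the files, so their tests and the genes named from them were chosen after their values were seen.

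The files do not pair circRNA probe identifiers with host genes or coordinates. The planned tests of 16 host gene lists and of circRNA classes were therefore not run, and no circRNA was matched to a gene symbol. The rule for named circRNAs, fixed before the data were examined, took the 10 largest changes past the adjusted threshold in each direction, and filled the places by smallest unadjusted p among probes with a fold of 1.5 or more and groups that did not overlap, plus the 3 brightest probes. At most 2 identifiers are printed per direction.

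The procedure was tested on simulated data with the real probe means and with the real residual spreads shuffled across probes. For the comparison of 14167 circRNA probes, 56.0% of 100 probes changed 2-fold and 86.0% of 100 probes changed 4-fold passed the adjusted threshold, with 11 unchanged probes also passing. For the 50 mRNA-accession probes, all of the 5 probes changed 2-fold and the 5 changed 4-fold passed, with 2 unchanged probes. The simulated arrays vary independently from probe to probe, unlike real ones.

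Alternatives were other normalizations (quantile, median, and the 75th percentile over probes above background on all arrays), normexp background correction with an offset of 50, other filters, other variance models, array weights, the authors' series table, the replicate number as a block, and each array left out. Normexp was planned on mean intensities and used median intensities, the column the files hold. All 6 arrays lay on 1 slide in 1 scan, so a slide or scan block did not apply. Array rows and columns on the slide were read from spot positions. The number of arrays limits the precision, and no circRNA spot was saturated.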

Results

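Circular RNAs, closed transcripts that resist exonuclease, were measured in mouse endometrium around the time of implantation, in a mouse model of polycystic ovary syndrome made with DHEA. The study asked how circRNAs of the receptive endometrium differ in that model. There were 3 arrays of DHEA-treated and 3 of oil-treated control pools, each of 3 mice. Between 98.2% and 99.8% of circRNA spots on an array were well above background. The same flag marked 94.3% of spots of the probes named as negatives, so it is a weak sign of specific signal. The 75th percentile of processed circRNA intensity was 277 ± 15.5 in DHEA and 259 ± 40.4 in control arrays (SD, n = 3 each; exact permutation p = 0.6). Across 94 other probes printed 10 times per array, replicate spots had a median SD of 0.046 on the log2 scale. The median residual SD of circRNA probes between pools of a group was 0.22.

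In the comparison of DHEA with control endometrium, ASCRP4010993 was 2.30-fold higher in DHEA (log2 difference 1.20, SE 0.12, limma adjusted p = 0.332). ASCRP4008249 was 4.70-fold higher (log2 difference 2.23, SE 0.29, adjusted p = 0.335). ASCRP4001842 was lower in DHEA, at 0.559 times its control level (log2 difference −0.84, SE 0.14, adjusted p = 0.335). ASCRP4010312 was lower as well, at 0.452 times its control level (log2 difference −1.15, SE 0.20, adjusted p = 0.335). The naming rule admitted only probes whose groups did not overlap, and none of these 4 passed the adjusted threshold. Normexp background correction gave 0.82 for ASCRP4010993 and 1.82 for ASCRP4008249. It gave −0.49 for ASCRP4001842 and −0.68 for ASCRP4010312, both dimmer than the brightest probe named as a negative.

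**Figure D1:**
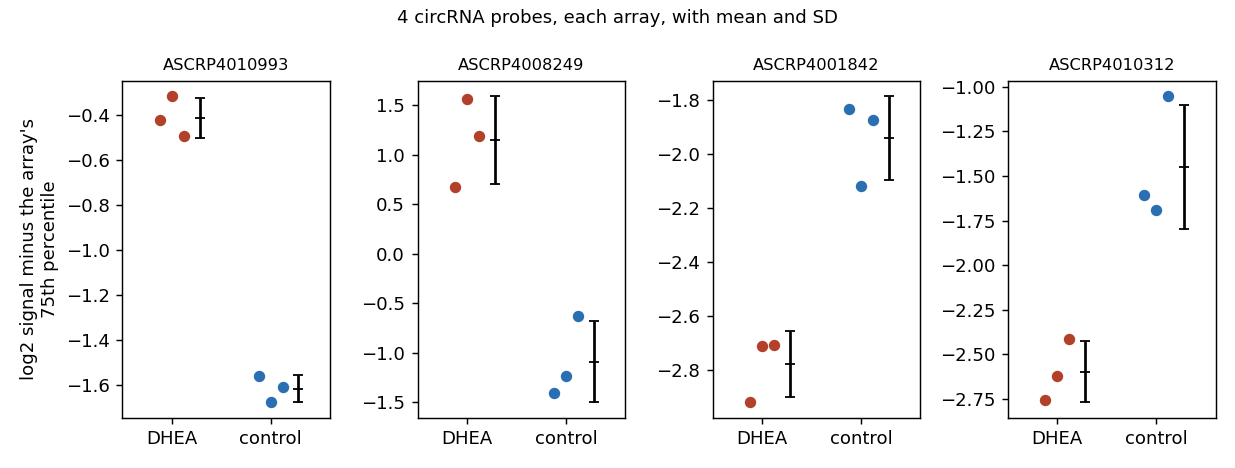
Log2 intensity relative to the 75th percentile of each array (vertical axes) for 4 circRNA probes, with 1 point per array and the mean and SD of the 3 arrays beside each group. Probes were chosen for groups that do not overlap, and the vertical scale differs between panels.

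The 10 circRNAs higher in DHEA with the smallest unadjusted p under the naming rule differed by 0.87 to 2.27 on the log2 scale, with standard errors of 0.12 to 0.31. The 10 lower in DHEA, chosen in the same way, differed by −1.94 to −0.77, with standard errors of 0.14 to 0.38. Of these 20 probes, 10 were brighter than the brightest negative-named probe. The 3 brightest circRNA probes had log2 differences of −0.15, −0.20 and −0.12, with adjusted p of 0.703, 0.667 and 0.798. Without control 1 these differences were −0.040, −0.041 and 0.0028. Both probes that were well above background on all 3 DHEA arrays and on no control array lay so near background that no fold could be bounded. No probe showed the opposite pattern.

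Across all 14167 circRNA probes, limma called 0 past an adjusted p of 0.05, and 1590 had an unadjusted p under 0.05, 1099 of them higher and 491 lower in DHEA. The test without empirical Bayes also called 0, with 1600 at an unadjusted p under 0.05, and limma with a variance trend and robust estimation called 0, with 1594. At an unadjusted p under 0.05 and a fold of 1.5 or more there were 529 circRNAs, 289 higher and 240 lower in DHEA, and 100 at a fold of 2 or more, 37 higher and 63 lower. The groups did not overlap for 2600 probes (18.4%), of which 1897 were higher and 703 lower in DHEA. Chance gives 10% on average over all splits of the arrays. Probes of 1 array vary together, so a single split can lie far from that average, and the share was not computed for other splits. After each array was scaled to its own circRNA probes, 50.6% of all probes were higher in DHEA, a share that this scaling largely sets. Array weights gave 3020 calls, but that estimate did not converge and put a weight of 40.2 on 1 array, DHEA 2. The 1590 became 610 without DHEA 2. More of them were higher than lower in DHEA with any 1 array omitted, but 906 were higher and 1461 lower without DHEA 3 and control 1. The list of 529 became 304 without DHEA 2, 1122 without DHEA 3 and 1127 without control 2, and its share higher in DHEA ranged from 37.8% to 66.6% over the 6 single omissions.

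**Figure D2:**
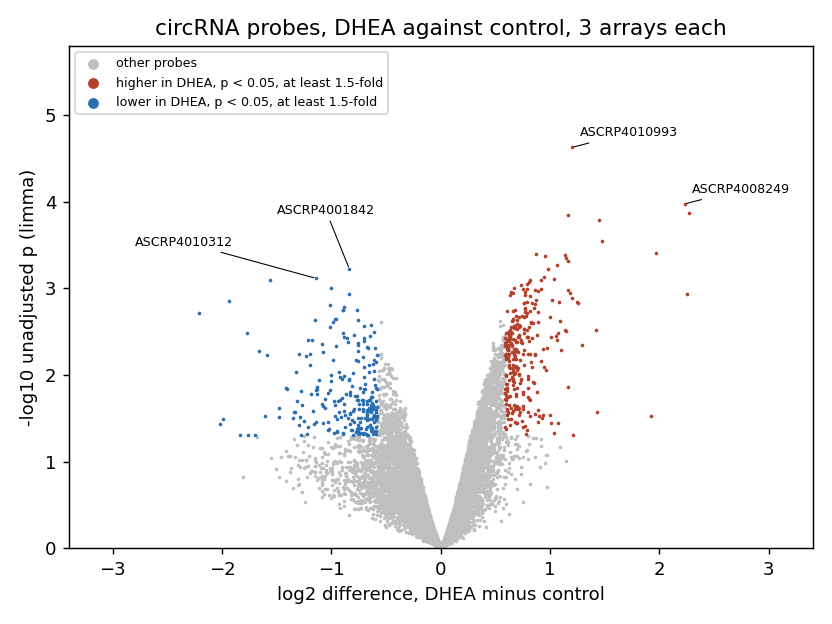
Log2 difference between DHEA and control (horizontal axis) against the −log10 unadjusted limma p (vertical axis), with 1 point per circRNA probe. Colours mark the 289 higher and 240 lower probes at an unadjusted p under 0.05 and a fold of 1.5 or more, none of which passed the adjusted threshold.

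The first principal component of the circRNA probes held 45.9% of the variance and did not part the groups, with DHEA 3 (34.4) and control 2 (27.3) at one end and control 1 (−33.9) and DHEA 1 (−26.9) at the other (exact permutation p = 1). The second held 31.5% and parted them, from 6.11 to 28.7 in DHEA and from −29.0 to −9.71 in control arrays (n = 3 each; exact permutation p = 0.1, the smallest possible). DHEA 3 correlated across probes at 0.990 with control 2, against 0.967 with DHEA 1 and 0.982 with DHEA 2.

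**Figure D3:**
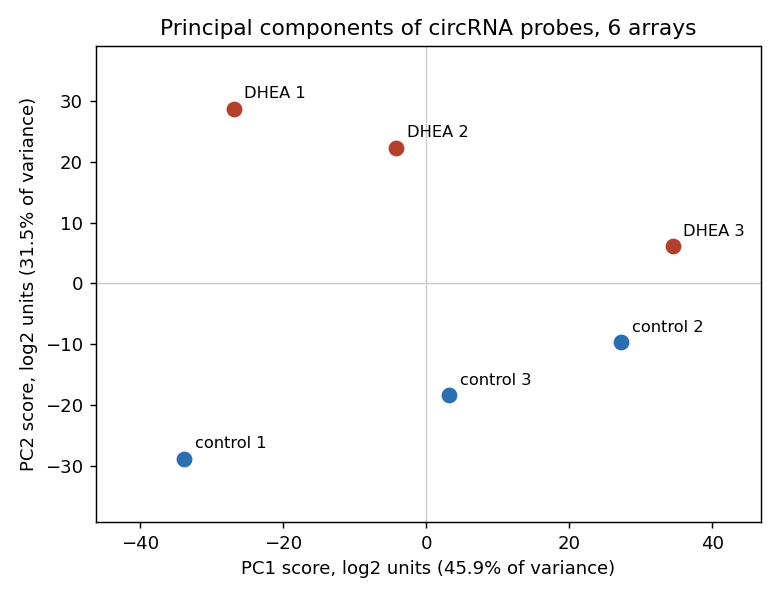
Scores of the 6 arrays on the first (horizontal) and second (vertical) principal components of circRNA probe levels in log2 units, coloured by group. The 3 DHEA arrays lie above 0 and the 3 control arrays below 0 on the second component, while the first mixes the groups.

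Linear transcripts were represented by the 50 mRNA-accession probes, read after RNase R digestion. Probes for Olfr1307, an olfactory receptor gene (log2 difference 0.72, SE 0.20), and H2-Q7, a nonclassical major histocompatibility gene (0.65, SE 0.21), were higher in DHEA, each at a limma adjusted p of 0.0925. Tm9sf1 (0.48, SE 0.14), Mzb1, a chaperone of antibody-secreting cells (0.47, SE 0.14), and Carhsp1 (0.53, SE 0.16) had the same adjusted p. Hyal3, of the hyaluronidase family, had a log2 difference of 0.40 (SE 0.14) and Lhfp of 0.84 (SE 0.30). The Lhfp difference was 0.45 without control 1. Lhx1, a homeobox transcription factor (0.37, SE 0.15), Prdx2, an antioxidant peroxiredoxin (0.35, SE 0.15), and Apoe, a lipid carrier (0.43, SE 0.19), were also higher at an unadjusted p under 0.05. Nup50, a nuclear pore component, was lower (−0.47, SE 0.20). With normexp correction the difference was 0.34 for Lhfp, 0.27 for Carhsp1, 0.29 for Mzb1 and −0.24 for Nup50. On average the Lhfp, Carhsp1, Mzb1, Nup50 and Atg3 probes were dimmer than the brightest probe named as a negative. Actb, encoding cytoplasmic actin, had a log2 difference of −0.04 (SE 0.43), and its sign turned under several alternatives. Atg3, which acts in autophagosome formation, differed by 0.07 (SE 0.14; 0.0064 without control 2, 0.015 without DHEA 1 and 0.14 without DHEA 3) and Pex11a, a peroxisome division gene, by −0.26 (SE 0.19), and the signs of both also turned under alternatives.

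By limma, 0 of these 50 probes passed an adjusted p of 0.05, with 14 at an unadjusted p under 0.05, 13 higher and 1 lower in DHEA. The test without empirical Bayes called 0, with 11 at an unadjusted p under 0.05. The groups did not overlap for 15 probes, all higher in DHEA, where chance gives 10% of probes on average over all splits. A single split can lie far from that average, since probes vary together. Normexp correction called 4 probes and array weights 7, while omitting control 2 called 4 and omitting control 1 or control 3 called 1. With the slide column as a block, which rests on 2 arrays per group, 3 probes had an unadjusted p under 0.05, and without DHEA 2 there were 6.

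**Figure D4:**
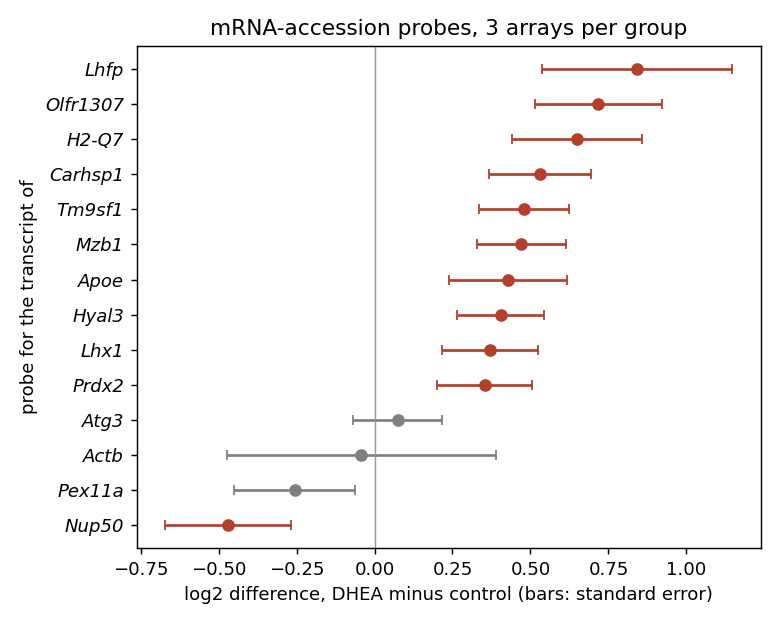
Log2 difference between DHEA and control (horizontal axis), with standard errors as bars, for the named mRNA-accession probes (vertical axis), 3 arrays per group. Coloured points had an unadjusted p under 0.05 and grey points did not. Nup50 lies at −0.47, and Lhfp lies at 0.84 but at 0.45 without control 1.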

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

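All tests in this part were chosen after the results they bear on were seen. Outliers were not looked for, since groups of 3 are too small for the rule used.

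Of the spots of the 15 probes named as negatives, 94.3% were well above background, against 0 of the 462 spots of Agilent's own negative controls, which is a signal in data outside the comparisons. Their mean signals ran from 7.58 to 115, and 55.4% of circRNA probes were dimmer than the brightest of them.

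In circRNA probes the 6 arrays parted more strongly as DHEA 1, DHEA 2 and control 1 against DHEA 3, control 2 and control 3 than by treatment. There were 85 past the adjusted threshold against 0 and 1191 on the looser list against 529. The mRNA-accession probes went the other way, with 4 at an unadjusted p under 0.05 for that split and 14 for the real one. The split was picked as the highest in circRNA probes, and DHEA 1, control 1 and control 3 against the rest also exceeded treatment, with 849 on the looser list. The lead of a split picked in this way does not decide whether the samples hold a structure other than treatment. A swap of the DHEA 3 and control 1 labels may be one source, but the correlation of control 1 with DHEA 1 and 2 was lower by 0.00196 (−0.00196) than with control 2 and 3, and the single values overlapped, while DHEA 3 correlated at 0.985 with control 2 and 3 against 0.975 with DHEA 1 and 2, so this stays open. Slide position may be another: arrays sharing a column had deviation correlations of 0.27 and 0.58, against at most 0.51 for other arrays across groups. The 14 circRNA-control probes, whose target the files do not give, followed the first component within groups (r = 0.98, two-sided exact permutation p = 0.0278, the smallest possible). The other kinds ran against it, with r = −0.82 for mRNA-accession, −0.79 for negative-named and −0.79 for custom probes (adjusted exact permutation p = 0.167 each). Over the 4 kinds of probe examined, the adjusted p of 0.111 for the circRNA-control probes is the smallest that 1 kind alone could reach. It therefore decides nothing, and differences between the pooled mice stay untested.

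The mRNA-accession probes leaned higher in DHEA, with 31 of 50 higher and a median log2 difference of 0.09. That median ranged from 0.053 to 0.18 with 1 array omitted. It was 0.033 with normexp, 0.0087 with the circRNA-control covariate, 0.22 with the slide row block and 0.24 without DHEA 3 and control 1. Scaling to the circRNA probes may contribute, but relative to the negative-named probes of the same array their mean was still higher in DHEA by 0.18 on the log2 scale (2.89 ± 0.07 against 2.71 ± 0.10, SD, n = 3 each; exact permutation p = 0.1, the smallest possible). All 3 DHEA arrays lay above the control arrays, the nearest at 2.84 and 2.81. If more linear RNA were left after digestion in the DHEA pools, the probes could shift alike, and 0 of the 50 departed from their common median at an adjusted p under 0.05 by limma's variances, with 10 at an unadjusted p under 0.05. Both explanations stay open, and an effect of DHEA on these transcripts was not tested apart from them.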

How the results depend on the processing

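Alternatives that use slide position, the circRNA-control probes, the negative-named probes or 2 omitted arrays, and all those for mRNA-accession probes, were chosen after seeing the data. No circRNA passed the adjusted threshold under any setting chosen before the data were examined except array weights (3020). That estimate stopped before convergence with a weight of 40.2 on DHEA 2, and other splits of the arrays under it gave up to 5393. Without DHEA 3 and control 1 together, 24 passed. With 10 splits of 3 against 3 the share cannot fall under 0.05. Every one of the 10 necessarily reaches the real count of 0 past the adjusted threshold (highest other 85). As many as 529 on the looser list from 3 (highest other 1191), and as many as 14 mRNA-accession probes from 1 (highest other 5).

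The looser list of 529 became 234 with normexp, 310 without empirical Bayes, 1522 with array weights, 100 at a fold of 2, and between 304 and 1127 with 1 array omitted. At an unadjusted p under 0.05 alone, 1590 passed (highest other split 2197, no block). The count was 610 without DHEA 2, 5484 with the unconverged array weights, 3429 with the circRNA-control covariate and 2472 with the slide column block. Without DHEA 3 and control 1, 906 were higher and 1461 lower. The looser list became 1214 with a slide column block, 1084 with a slide row block, 1110 in slide row 1, 1874 with the circRNA-control covariate, 285 above the brightest negative-named probe, and 1461 without DHEA 3 and control 1. Slide row and treatment are nearly confounded, since row 2 held no control array, so the row block and row 1 both set DHEA 1 alone against the controls, and in row 1 the lone array is assumed to vary like them. The column block rests on the 2 columns that held both groups, and so not on DHEA 1 or control 3. The authors' values gave 374, of which 312 were among the 529. Its share higher in DHEA, 54.6%, was 74.2% without empirical Bayes, 38.0% with array weights, 37.8% to 66.6% with 1 array omitted, 36.2% with the row block, 31.3% in slide row 1 and 22.6% without DHEA 3 and control 1. The cause was not tested, beyond the stricter fold, the filter and the fewer arrays.

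The 50.6% of all probes higher in DHEA became 52.2% with quantile normalization, 41.3% with normexp, 53.2% with array weights, 52.5% in the authors' values, 53.5% with the covariate, 55.1% without DHEA 3 and control 1, and 50.1% to 52.7% with 1 array omitted. The median log2 difference (0.0048) became −0.033 with normexp, 0.023 with array weights, 0.031 with the covariate, 0.040 without both arrays and 0.00025 to 0.019 with 1 array omitted. The cause was not tested.

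With the replicate number as a block, 0 circRNAs and 0 mRNA-accession probes passed, and the looser list held 672 with 43.2% higher in DHEA. Deviations of same-numbered arrays correlated at 0.51, −0.33 and 0.10, too few values to decide on pairing.

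For mRNA-accession probes, 4 passed the adjusted threshold with normexp, 7 with array weights and 0 to 4 with 1 array omitted. The 14 at an unadjusted p under 0.05 became 9 with median centring, 3 with the column block, 7 with the row block, 5 in slide row 1 and 6 to 15 with 1 array omitted. The Actb difference turned to 0.18 with array weights, 0.54 with the row block and in slide row 1, and 0.69 without both arrays, and was as high as 0.44 and as low as −0.46 with 1 array omitted. With the covariate it was −0.94 (adjusted p = 0.0559 by limma, 0.0559 to 0.968 over the alternatives). Atg3 turned to −0.010 with normexp and −0.056 with the covariate, and Pex11a to 0.023 with the row block and in slide row 1 and 0.032 without both arrays (−0.40 to −0.088 with 1 array omitted). Of the brightest circRNAs, which quantile normalization ties at the top ranks, 1 turned to 0.00083 with it, 0.054 with array weights, 0.067 in the authors' values, between −0.20 and 0.0028 with 1 array omitted and 0.0088 without both arrays, and another to 0.00058 with quantile normalization. Alternatives that change only the filter or the variance model leave a difference as it was. The circRNAs chosen for groups that did not overlap could not turn when 1 array was omitted. Of 432 values of named probes under alternatives, 393 kept direction and side of the threshold and 18 turned, shares that these limits partly set. Among those that kept direction, H2-Q7 was 0.28 with the row block, Apoe 0.17 and Prdx2 0.21 with the covariate, and Nup50 −0.23 and Lhx1 0.23 with the column block. The cause was not tested. The planned host gene list and circRNA class tests were not run, nor a slide or scan block, since all arrays shared 1 slide and scan. Signal over background limits the dimmest probes, as 7.84% of circRNA probes lay below the median negative-named probe.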

Other observations

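The 15 custom probes, whose targets the files do not give, included 2 higher in DHEA at an unadjusted p under 0.05 and 0 past the adjusted threshold by limma (smallest adjusted p 0.0655). The 14 circRNA-control probes had a mean relative level of −0.14 ± 0.54 in DHEA and 0.42 ± 0.37 in control arrays (SD, n = 3 each; exact permutation p = 0.3). All 14 were lower in DHEA, though probes of 1 array vary together, and 0 passed the adjusted threshold by limma.

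In the slide column that held DHEA 2 and control 1, ASCRP4008249 was higher in DHEA by 2.97 on the log2 scale and ASCRP4010993 by 1.24. In the column of DHEA 3 and control 2 the differences were 2.42 and 1.18. ASCRP4001842 differed by −0.88 and −0.59 in these columns, and ASCRP4010312 by −1.01 and −0.72. These probes were chosen for groups that did not overlap, so the direction within each column was fixed in advance.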
